A study of Rattus norvegicus with 6 samples.

How the data were processed

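Gene expression was measured by RNA sequencing of rat brain tissue in 6 libraries, 3 of a control group and 3 of a hypoxia-ischemia (HI) group. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were prepared with a SMARTER mRNA-Seq kit. Per the submitters' processing notes, HISAT2 2.1.0, SAMtools 1.10, StringTie 2.2.1 and the rat assembly Rnor 6.0 were used. The counting step, its annotation and its treatment of strand and of shared reads are not given in the sources used here.

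The deposited table holds estimated counts, with no scaling, for 19382 genes, each with a gene number and a symbol per the file headers. Of all entries 8.87% were not whole to within 1e-09, in 2410 genes, and these held 8.77% to 9.55% of the reads of a library, so reads that match several genes appear to have been divided among them. Genes with such entries are called genes with shared reads and their values are uncertain. Among the genes named in the text these were Exoc7, Oas1g, P2rx7, Pfkfb4, LOC108348108, Atf3, Plac8, Enpp6, Otx2, Oas1a, Mt2A, Cox7a2, Cycs, Kdm5d, Kdm6a and Eno2. All 6 columns were used, each matched to its sample by name, and the label of control 1 is spelled with a missing letter in the table. There were 296 genes at 0 in every library, and 27 rows carried a calendar date in place of a symbol, as spreadsheet software makes of some gene names, and were kept under their gene numbers. Of the gene numbers 17983 (92.8%) were found in a reference gene table of assembly GRCr8, which was used for older symbols (11 list members) and for the span of genes, and from which no coordinate is given.

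Groups and replicate numbers were taken from the sample titles and treatment labels. No library pair was a duplicate, since the chi-square statistic per degree of freedom between libraries, over genes with at least 10 reads in the pair, ran from 13.4 to 162, and Spearman correlations of log2 CPM ran from 0.941 to 0.985 across genes, which are not independent replicates. The first principal component took 57.4% of the variance and separated the groups, with controls between -55.0 and -46.1 and HI libraries at 15.1, 48.8 and 83.3.

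Estimated counts were rounded to whole numbers, filtered with filterByExpr of edgeR (minimum count 10) and scaled by TMM. Normalization factors were 0.922, 0.925 and 0.960 in the controls and 1.045, 1.056 and 1.107 in HI. The comparison used the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), two-sided, with group as the only term and all 6 libraries sharing the estimate of the spread. The common biological coefficient of variation was 0.275. P-values were adjusted by Benjamini-Hochberg over 14959 genes with a threshold of 0.05. Levels are CPM with TMM factors, as mean ± SD over the 3 libraries of a group, fold changes come from the edgeR fit, and their SE was derived from the F statistic. For a gene at 0 in all controls the fold was computed against 3 reads per library. Floors cover counting error only, 95% bootstrap intervals of list medians cover the spread between genes and not that between libraries, and reads of amplified libraries without molecular identifiers are not independent molecules.

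Lists of genes for pathways, cell types, brain regions and sample quality, 35 in number, were fixed together with the tests, the named-gene rule and most alternatives before the data were examined. Each list with at least 3 tested members was compared with all other tested genes by camera of limma, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with a correlation estimated per list, and fry, which tests whether a list's own genes move on balance in 1 direction, served as alternatives. The estimated correlation allows for members that vary together between libraries and ended all of the list calls. The list of mitochondrially encoded genes was not analysed here. Another 4 lists, of cerebral cortex, hypothalamus, basal forebrain and Y-linked genes, were added after the data were seen. Their p-values were adjusted over these 4 lists alone.

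Genes named in the text are the 11 genes of the studied axis whatever their result, then the 10 largest rises and the 10 largest falls among genes with a symbol, an adjusted p below 0.05, a mean of at least 1 CPM and non-overlapping groups, and from each list the 4 members with the smallest p where the list passed or had at least 2 called members, otherwise up to 2. This rule named 137 tested genes, of which a few are not reported here. Genes named beyond it are marked as chosen after their values were seen.

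Alternatives were scaling by DESeq2 size factors, by upper quartiles and by total counts, the Wald test of DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in at least 3 libraries, a robust dispersion, thresholds of 0.01 and 0.1, the replicate number as a block, and leaving out each library. The table held no row without a gene number, so leaving such rows out was not run. Chosen after the data were seen were a covariate for the presence of Y-linked reads (at least 10 reads of Kdm5d and Eif2s3y), covariates for the median level of the choroid plexus list and of the red blood cell list, and fits without control 2, HI 2 and HI 3 or without controls 1 and 2.

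The procedure was tested on simulated data made from the means and library sizes of this comparison, over 14959 genes. For HI against control edgeR called 32.0% of 100 genes changed 2-fold and 73.0% of 100 changed 4-fold, with 8 false calls among 113. DESeq2 called 66.0% and 81.0% with 52 false calls among 199, and voom 31.0% and 69.0% with 6 among 106. In 5 simulations of the list test a list of 20 genes changed 2-fold was called in 5, and 1 of 169 unchanged lists was called, or 5 and 0 with an estimated correlation. Simulated genes varied independently of each other, whereas the estimated correlation of the interferon list in the data was 0.878. The simulations therefore do not show how often unchanged lists are called where members vary together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.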

Results

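RNA from rat brain tissue was sequenced in 6 libraries, 3 from control rats and 3 from rats subjected to hypoxia-ischemia (HI) for 2.5 h at 7 days of age, a model of neonatal brain injury. The labels give neither the brain region taken, the time between the injury and sampling, nor the age of the controls. Estimated reads per library came to 14336687, 14692505 and 13922663 in controls 1, 2 and 3, and to 14324303, 14747426 and 14927469 in HI 1, 2 and 3. At that depth 3 reads, the limit that a count of 0 allows, correspond to 0.221 to 0.227 CPM in the controls and 0.182 to 0.201 CPM in HI. CPM are reads scaled to library size and TMM factor. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may in part be technical.

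The single comparison of the design, HI against control, asks which transcripts differ in the brain after the injury. In lists fixed beforehand 27 of 32 interferon-stimulated, 13 of 21 phagocyte and 17 of 30 reactive astrocyte genes rose in HI, and 13 of 26 excitatory neuron and 19 of 20 cholesterol synthesis genes fell. Each of these lists passed camera, a test of a list against all other genes, but none with its own correlation (adjusted p = 0.41 with an estimated correlation for each). Gfap, the intermediate filament of astrocytes, rose from 142 ± 5.16 to 1549 ± 696 CPM (SD, n = 3 per group), a log2 fold change of 3.45 ± 0.34 (SE). Gpnmb, a glycoprotein of lipid-laden phagocytes, rose from 11.2 ± 2.93 to 181 ± 78.4 CPM, and C1qc, a chain of complement C1q made by microglia, from 7.25 ± 1.17 to 54.0 ± 16.8 CPM. Camk2a, a kinase of excitatory synapses, fell from 157 ± 28.9 to 49.3 ± 3.98 CPM, and Hmgcs1, an enzyme of the mevalonate pathway, from 1092 ± 250 to 313 ± 65.7 CPM.

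Of 14959 genes tested, 2074 changed, 1021 higher and 1053 lower in HI (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p below 0.05), and 1237 of these by at least 2-fold, 769 higher and 468 lower. The edgeR adjusted p of the called genes lay between 0.0196 and 0.0499, and 0 genes were under 0.01. At an unadjusted p below 0.05 there were 5460 genes, and the groups did not overlap for 6329 genes (42.3%, where chance gives 10%). DESeq2 called 4200 genes and limma-voom 1371. With other scalings the share of called genes that were higher in HI moved from 49.2% to 64.3% with upper-quartile factors and 74.7% with total counts, which shifted the median of all genes by 0.10 and 0.19 on the log2 scale, and limma-voom gave 40.3%. The count rested on single libraries. It was 0 genes without control 1, 1 without control 2, 0 without HI 2, 644 without HI 3, 1694 without control 3 and 3689 without HI 1 by edgeR, with 3962, 4008, 4175, 4220, 5261 and 6391 genes at an unadjusted p below 0.05, and 0 of the 2074 calls held without control 1, control 2 or HI 2. All 2074 genes had the same sign in each of the 6 fits. As they were chosen on these libraries, that outcome was largely fixed in advance and is not evidence that the changes hold.

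Among the 10 largest rises of genes with separated groups and a mean of at least 1 CPM, Itgax, an integrin of activated microglia and dendritic cells, rose from 0.05 ± 0.04 to 5.13 ± 3.97 CPM, and Lgals3, a lectin of phagocytes, from 1.18 ± 0.82 to 61.0 ± 35.9 CPM. Clec7a and Clec12a, receptors of myeloid cells, rose 30.6-fold and 28.4-fold, the myeloid hexokinase Hk3 47.5-fold, the stress-induced pseudokinase Trib3 45.1-fold, the smooth muscle protein Tagln 32.8-fold and the ubiquitin-like interferon product Isg15 29.5-fold. Reads in a control were at most 1 for Itgax, Clec7a and Clec12a, 2 for Trib3, 4 for Hk3 and 5 for Isg15. For all of these but Isg15 the control mean lay below the limit of 3 reads, and the size of their folds is uncertain. Exoc7, a subunit of the exocyst, and Oas1g, an interferon-induced synthetase, had no read in any control, so their rises were at least 49.9-fold and 18.4-fold against a floor of 3 reads per library. As both share reads with similar genes, their values are uncertain. The edgeR adjusted p of these 10 genes lay between 0.0207 and 0.0247, and all 3 HI libraries stood above all 3 controls. Among the largest falls, Emx1, a transcription factor of the dorsal telencephalon, fell from 31.9 ± 24.4 to 1.46 ± 0.72 CPM (edgeR adjusted p = 0.0344), with 541, 687 and 57 reads in controls 1 to 3 and 11, 23 and 36 in the HI libraries. Mef2c, which regulates neuronal maturation, fell to 0.107 of the control level and was also lower in control 3 than in the other controls. Mas1, Usp43, Rxfp1, Eya4, Fzd10 and the organic cation transporter Slc22a3 fell to between 0.0430 and 0.108 of the control level. All 6 were lowest among the controls in control 3 as well, with CPM in controls 1, 2 and 3 of 21.7, 14.0 and 1.80 for Mas1, 33.6, 52.8 and 6.36 for Usp43, 25.2, 19.7 and 4.94 for Rxfp1, 4.77, 7.44 and 1.20 for Eya4, 17.0, 10.2 and 7.34 for Fzd10 and 47.4, 55.2 and 11.8 for Slc22a3. By limma-voom the falls of Emx1, Mas1, Usp43, Rxfp1, Eya4 and Slc22a3 did not pass (adjusted p from 0.0720 to 0.158). Dio2, which activates thyroid hormone, fell from 49.8 ± 19.2 to 5.28 ± 2.39 CPM (edgeR adjusted p = 0.0215).

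The submitters' title names the TLR4 and NF-kB pathway, inflammation and pyroptosis. Myd88, the adaptor of Toll-like receptors, rose from 4.61 ± 0.68 to 13.6 ± 5.04 CPM (log2 fold change 1.55 ± 0.31 SE, edgeR adjusted p = 0.0305). Tlr4 itself stood at 1.19 ± 0.21 CPM in controls and 2.62 ± 0.65 CPM in HI, a log2 fold change of 1.13 ± 0.33 that did not pass the test (edgeR adjusted p = 0.0646), although all 3 HI libraries lay above all 3 controls. The NF-kB subunits Nfkb1 and Rela did not pass either, with log2 fold changes of 0.83 ± 0.27 (edgeR adjusted p = 0.0762) and 0.33 ± 0.21 (edgeR adjusted p = 0.306). Another subunit, Nfkb2, did pass (edgeR adjusted p = 0.0285). Within the pyroptosis machinery, the inflammasome sensor Nlrp3 rose 2.98-fold, the protease Casp1 4.53-fold and the pore-forming protein Gsdmd 3.22-fold, with edgeR adjusted p of 0.0493, 0.0351 and 0.0281. Il18, a substrate of Casp1, had a log2 fold change of 1.64 ± 0.58 and did not pass (edgeR adjusted p = 0.0958). Reads of the cytokines Il1b, Tnf and Il6 were too few to pass the filter. In the edgeR fit without a filter their adjusted p were 0.58, 0.76 and 0.30. Il1b had 0, 2 and 4 reads in the controls and 1, 5 and 8 in HI, Tnf 2, 4 and 1 against 5, 0 and 0, and Il6 1, 0 and 0 against 1, 2 and 3, so a difference was not detectable at this depth. Over 20 other settings, 10 called Myd88, 7 Nlrp3, 11 Casp1, 10 Gsdmd, 4 Nfkb1 (DESeq2 adjusted p = 0.0251), 2 Tlr4, 1 Rela and 0 Il18. Their edgeR, DESeq2 or limma adjusted p ranged from 6.5e-05 for Gsdmd with DESeq2 to 0.910 for Rela with a choroid plexus covariate.

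**Figure D1:**
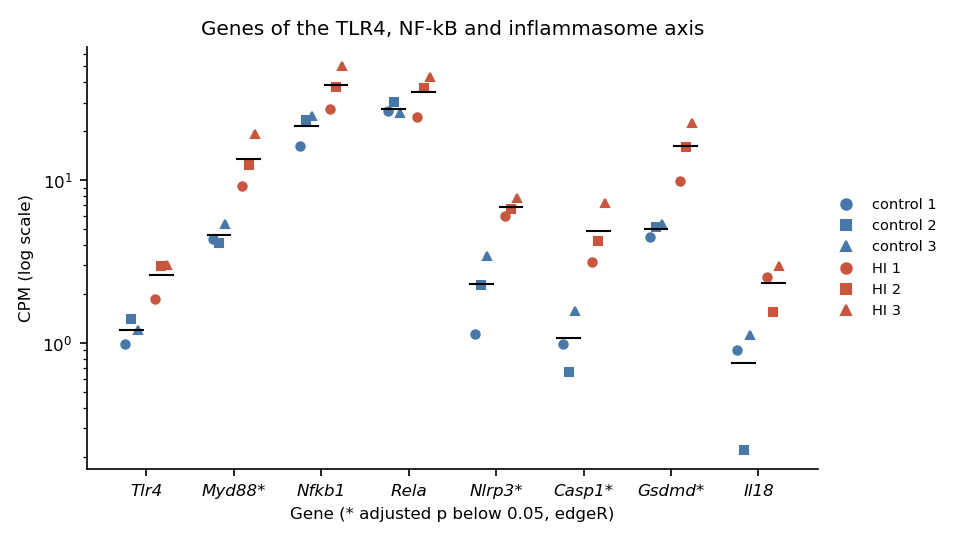
Expression of the 8 tested genes of the TLR4, NF-kB and inflammasome axis in each library, in CPM on a log scale, with controls in blue, HI in red and the group mean as a line. All HI libraries lie above all controls for each of these genes except Rela, and an asterisk marks Myd88, Nlrp3, Casp1 and Gsdmd, which passed the edgeR test.

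Inflammatory signalling genes were examined as 3 lists fixed around that theme. In the TLR4 and NF-kB signalling list 5 of 32 tested genes rose and 0 fell, or 12 and 0 adjusted over the list alone, with a median log2 fold change of 0.40. Besides Myd88, the lipopolysaccharide co-receptor Cd14 rose 12.8-fold, the NF-kB subunit Nfkb2 3.80-fold and the nuclear NF-kB regulator Bcl3 12.9-fold, and Tab2, a kinase adaptor named after its value was seen, had a log2 fold change of 0.37. This list passed camera (adjusted p = 8.5e-04), but not with its own correlation (adjusted p = 0.53 with an estimated correlation). Among cytokines and chemokines 10 of 31 genes in the table could be tested, and 3 rose and 0 fell, or 7 and 0 adjusted over the list alone. Cxcl16, a chemokine of phagocytes, rose 6.83-fold, the microglial growth factor Csf1 2.91-fold and Tgfb1 2.74-fold, whereas Ccl2, which attracts monocytes, had a log2 fold change of 3.42 ± 0.92 that did not pass (edgeR adjusted p = 0.0544). The median was 1.59, also with Cxcl10, which had no read in the controls, set to its lower bound (camera adjusted p = 4.0e-04, and adjusted p = 0.41 with an estimated correlation). Ccl2 had at most 8 reads in a control. Like Cxcl10 it passed the filter through its HI reads, which tilts the median upward. Of 18 inflammasome and pyroptosis genes 9 rose and 1 fell, or 11 and 1 adjusted over the list alone, with a median of 1.28 (camera adjusted p = 1.5e-03, and adjusted p = 0.41 with an estimated correlation). Txnip, a thioredoxin inhibitor that binds Nlrp3, rose 3.20-fold and the ATP-gated channel P2rx7 2.1-fold. As the title of this series names the theme, the direction of these 3 lists is not taken as independent evidence.

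Of 20 microglia markers 14 rose and 0 fell, or 16 and 0 adjusted over the list alone, with a median log2 fold change of 1.33. The complement genes C1qa, C1qb and C1qc rose 5.46-fold, 5.16-fold and 7.44-fold, and Ptprc, the pan-leukocyte surface protein CD45, 5.20-fold. P2ry12, P2ry13, Tmem119 and Sall1, markers of resting microglia named after their values were seen, had log2 fold changes of -0.13, -0.02, 0.48 and 0.44 and did not pass. Among activated microglia and phagocyte genes 13 of 21 rose and 0 fell, or 17 and 0 adjusted over the list alone, with a median of 1.84. Gpnmb rose 16.1-fold, the heme-degrading enzyme Hmox1 5.25-fold and Axl, a receptor for apoptotic cells, 2.93-fold. The phagocyte members Itgax and Clec7a had at most 1 read in a control and passed the filter through their HI reads, which tilts that median upward. Both lists passed camera (adjusted p = 4.1e-11 and 7.9e-12), but not with their own correlation (adjusted p = 0.41 with an estimated correlation for each). Of 27 blood leukocyte genes with a row, 18 had fewer than 10 reads in every library, and the neutrophil genes S100a8 and S100a9, named after their values were seen, had at most 12 and 5. Of the 7 that could be tested 4 rose and 0 fell, or 5 and 1 (Vcan) adjusted over the list alone, with a median of 2.91. Those that rose were Mmp9 (11.1-fold), Cd8a (12-fold), Csf3r (3.03-fold) and Plac8 (7.50-fold, with shared reads). Mmp9, Cd8a and Plac8 had at most 6, 6 and 8 reads in a control and passed the filter through their HI reads, which tilts the median upward. The T-cell genes Cd3e, Cd3d and Cd3g, named after their values were seen, had at most 1 read in any library, so Cd8a is not taken as a sign of T cells. Border macrophage markers had a median of 2.01, and 3 of 7 rose and 0 fell, or 5 and 0 adjusted over the list alone, with Folr2 at 15.7-fold, Clec10a at 4.90-fold and the mannose receptor Mrc1 at 4.03-fold, while Cd163 had a log2 fold change of 2.51 ± 0.68 that did not pass. Folr2, Clec10a and Cd163 had at most 5, 6 and 9 reads in a control. They also passed the filter through their HI reads, which tilts the border macrophage median upward. The leukocyte and border macrophage lists passed camera (adjusted p = 1.6e-03 and 8.5e-04), but not with their own correlation (adjusted p = 0.41 and adjusted p = 0.46 with an estimated correlation).

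Interferon-stimulated genes rose together. Of 32 tested 27 rose and 0 fell, or 32 and 0 adjusted over the list alone, with a median log2 fold change of 2.81 (camera adjusted p = 4.0e-19, and adjusted p = 0.41 with an estimated correlation). The antiviral genes Isg15, Oas1a and Ifi44 rose 29.5-fold, 14.2-fold and 7.0-fold, and the immunoproteasome subunit Psmb8 10.9-fold. Isg15 had at most 5 reads in a control, so the size of its fold is uncertain. In complement and antigen presentation 19 of 24 genes rose and 0 fell, or 23 and 0 adjusted over the list alone, with a median of 2.26 (camera adjusted p = 2.7e-18, and adjusted p = 0.41 with an estimated correlation). C5ar1, a receptor for a complement fragment, rose 9.21-fold and Cd74, the invariant chain of MHC class II, 8.47-fold. The interferon list median, relative to the control mean, was 1.60 in HI 1, 2.33 in HI 2 and 3.37 in HI 3, and lay between -0.01 and 0.07 in the controls. The choroid plexus list had medians of 0.55, 4.16 and 5.0 in HI 1, 2 and 3 and of 2.63 in control 2. Reads of Y-linked genes were present in control 3, HI 2 and HI 3 and at 0 in the other libraries. Among libraries without such reads the interferon median differed by 1.66 between HI and control and among those with them by 2.67, and the microglia median by 0.98 and 1.16. The former sets HI 1 alone against controls 1 and 2, and the latter HI 2 and HI 3 against control 3 alone. Each difference thus rests on a lone library on 1 side, and its spread is not known.

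Reactive astrocyte genes rose, and general astrocyte markers did not pass as a list. Of 30 reactive astrocyte genes 17 rose and 0 fell, or 22 and 0 adjusted over the list alone, with a median log2 fold change of 2.18, also with Cxcl10 set to its lower bound (camera adjusted p = 4.2e-12, and adjusted p = 0.41 with an estimated correlation). Besides Gfap, the intermediate filament Vim rose 10.4-fold, the small heat shock protein Hspb1 20.1-fold and the copper-binding ferroxidase Cp 6.68-fold. Of 17 astrocyte markers 1 rose, the water channel Aqp4 (1.94-fold), and 0 fell, with the same counts adjusted over the list alone and a median of 0.40 (camera adjusted p = 0.066). Mlc1, a membrane protein of astrocyte endfeet, had a log2 fold change of 0.77 ± 0.22 and did not pass. The astrocyte list passed without control 3 (camera adjusted p = 1.4e-03) and without HI 2 (camera adjusted p = 7.4e-03).

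Genes of excitatory neurons and glutamate synapses fell. Of 26 tested 0 rose and 13 fell, or 0 and 16 adjusted over the list alone, with a median log2 fold change of -1.30 (camera adjusted p = 4.1e-11, and adjusted p = 0.41 with an estimated correlation). Camk2a and Camk2b fell to 0.315 and 0.366 of the control level, and the glutamate receptor subunits Gria3 and Grin2a to 0.413 and 0.273. Among general neuron markers 0 of 23 rose and 6 fell, or 1 and 12 adjusted over the list alone, with a median of -0.85 (camera adjusted p = 3.3e-08, and adjusted p = 0.45 with an estimated correlation). The neuronal splicing factor Rbfox3 fell to 0.412, the synaptic vesicle fusion protein Snap25 to 0.477, the microtubule regulator Stmn3 to 0.570 and the surface glycoprotein Thy1 to 0.489 of the control level. Eno2 had erratic reads, 4, 6 and 29 in the controls against 466, 8 and 215 in HI, and it was the list's member counted as risen over the list alone, named here after its values were seen. Of 19 inhibitory neuron genes 0 rose and 0 fell by edgeR, over all genes and adjusted over the list alone, with 5 at an unadjusted p below 0.05 and 4 called by DESeq2. Their median was 0.09, their mean -0.21 and the direction of camera down (adjusted p = 0.62), so the sign differed between these measures. Pvalb, of fast-spiking interneurons, had a log2 fold change of -2.94 ± 0.78 and Calb2 one of 0.92 ± 0.28, and neither passed. The cortical gene Emx1 was low in control 3 as well as in HI, and against control 3 alone the excitatory median was -0.86.

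Of 21 oligodendrocyte lineage genes 0 rose and 3 fell, the same adjusted over the list alone, among them Mbp to 0.288 and Enpp6 to 0.257 of the control level, the latter with shared reads. The myelin genes Mag, Mog and Cnp, the latter 2 named after their values were seen, had log2 fold changes of -1.14 ± 0.35, -0.64 and 0.03 and did not pass. The median was -0.25 (camera adjusted p = 5.6e-03, and adjusted p = 0.56 with an estimated correlation). The call was lost without control 3 (camera adjusted p = 0.13) and without HI 1 (camera adjusted p = 0.061).

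Cholesterol synthesis genes fell almost as a block. Of 20 tested 0 rose and 19 fell, the same adjusted over the list alone, with a median log2 fold change of -1.20 (camera adjusted p = 1.2e-19, and adjusted p = 0.41 with an estimated correlation). Hmgcs1 fell to 0.287, the isomerase Idi1 to 0.341, the epoxidase Sqle to 0.481 and Stard4, which carries cholesterol between membranes, to 0.344 of the control level. The member that did not pass was Pmvk, with a log2 fold change of -0.35. This list and the excitatory list also passed fry, which asks whether genes move one way on balance (adjusted p = 0.047 and 0.035), and 0 of the 34 lists passed camera with an estimated correlation. Nuclear-encoded respiratory chain genes had a median of -0.15, which turned to 0.04 with total counts. Of 32 tested 0 rose and 1 fell, Cox5a to 0.714 of the control level, with 0 calls adjusted over the list alone, 7 genes at an unadjusted p below 0.05 and 7 called by DESeq2. Cox7a2, Cycs and Cox6c had log2 fold changes of -0.33, -0.47 and -0.36 and did not pass. That list passed camera (adjusted p = 0.029), but not with an estimated correlation (adjusted p = 0.63 with an estimated correlation), without control 3 (adjusted p = 0.13) or without HI 1 (adjusted p = 0.11).

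Among stress programmes, unfolded protein and integrated stress response genes and heat shock proteins rose in part, while targets of the hypoxia-inducible factor HIF did not pass as a list. In the unfolded protein list 8 of 24 rose and 0 fell, or 10 and 0 adjusted over the list alone, with a median log2 fold change of 0.59 (camera adjusted p = 1.2e-05, and adjusted p = 0.46 with an estimated correlation). Trib3 rose 45.1-fold, the transcription factor Atf3 24.8-fold with shared reads, the leucine sensor Sesn2 3.26-fold and Phgdh, an enzyme of serine synthesis, 2.11-fold. Trib3 had at most 2 reads in a control, so the size of its fold is uncertain. Of 19 heat shock proteins 5 rose and 0 fell, or 6 and 0 adjusted over the list alone, with a median of 0.22 (camera adjusted p = 5.0e-04, and adjusted p = 0.49 with an estimated correlation). Hspb1 rose 20.1-fold, Hspb8 5.78-fold, their partner Bag3 2.92-fold and LOC108348108, the table's entry for Hspa1b, 15.9-fold with shared reads, and the chaperone Cryab, named after its value was seen, had a log2 fold change of 1.92. Of 32 HIF targets 2 rose and 0 fell, or 1 and 0 adjusted over the list alone, with a median of 0.02, which turned to -0.01 with DESeq2 size factors (camera adjusted p = 0.87). Angptl4, which inhibits lipoprotein lipase, rose 5.17-fold and the hexokinase Hk2 2.12-fold, and Ndrg1 and Pfkfb4 had log2 fold changes of -1.40 ± 0.38 and -0.62 ± 0.17 that did not pass.

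Immediate early genes went both ways. Of 31 tested 5 rose and 3 fell, or 10 and 3 adjusted over the list alone, with a median log2 fold change of 0.91 (camera adjusted p = 0.061, and 4.0e-03 without HI 1). Fosl1 rose 11.8-fold, as did, named after their values were seen, Jun, Dusp1, Btg2 and Klf4 with log2 fold changes from 0.94 to 1.36, while Homer1, Egr3 and Nr4a2, which neuronal activity induces, fell to 0.439, 0.330 and 0.231 of the control level. In the p53 and apoptosis list 7 of 25 rose and 2 fell, or 11 and 2 adjusted over the list alone, with a median of 0.56 (camera adjusted p = 1.1e-03, and adjusted p = 0.49 with an estimated correlation). The death receptors Fas and Tnfrsf1a rose 15.1-fold and 3.32-fold and the p53 targets Phlda3 and Tp53inp1 3.15-fold and 2.35-fold, whereas the members that fell included Apaf1, of the apoptosome, named after its values were seen. Of 24 oxidative stress and iron genes 6 rose and 1 fell, or 8 and 1 adjusted over the list alone, with a median of 0.43 (camera adjusted p = 1.2e-03, and adjusted p = 0.46 with an estimated correlation). The metallothioneins Mt2A and Mt1 rose 15.0-fold and 5.92-fold, the former with shared reads, Hmox1 5.25-fold and the quinone reductase Nqo1 2.95-fold, and the member that fell was the transferrin receptor Tfrc, with a log2 fold change of -0.89, named after its value was seen.

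Of 24 endothelial and pericyte markers 5 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a median log2 fold change of 0.97 (camera adjusted p = 7.7e-05, and adjusted p = 0.53 with an estimated correlation). The contractile genes of mural cells Tagln, Acta2 and Myh11 rose 32.8-fold, 5.62-fold and 2.50-fold and the endothelial gene Egfl7 2.79-fold, and the endothelial cadherin Cdh5, named after its value was seen, had a log2 fold change of 1.22. In matrix remodelling and fibrinolysis 8 of 23 rose and 0 fell, or 10 and 1 (the proteoglycan gene Vcan) adjusted over the list alone, with a median of 1.13 (camera adjusted p = 7.8e-05, and adjusted p = 0.52 with an estimated correlation). The protease inhibitors Timp1 and Timp3 rose 12.5-fold and 1.89-fold, Mmp9 11.1-fold and the urokinase gene Plau 12-fold. Of 24 cell cycle genes 2 rose and 0 fell, or 10 and 0 adjusted over the list alone, with a median of 0.65 (camera adjusted p = 7.8e-05, and adjusted p = 0.54 with an estimated correlation). The replication gene Mcm3 rose 2.27-fold and the proliferation marker Mki67 1.64-fold, while Rrm2 and Bub1b had log2 fold changes of 0.58 ± 0.16 and 0.78 ± 0.22 and did not pass. HI 1 lay little above the controls in the endothelial list, with a median of 0.18 against 0.16 in control 3. In the matrix list it was at 0.319 against 0.245 in control 2, while HI 2 and HI 3 were at 1.145 and 1.795. Without control 2, HI 2 and HI 3 the endothelial and cell cycle calls ended (camera adjusted p = 0.086 and 0.22).

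**Figure D2:**
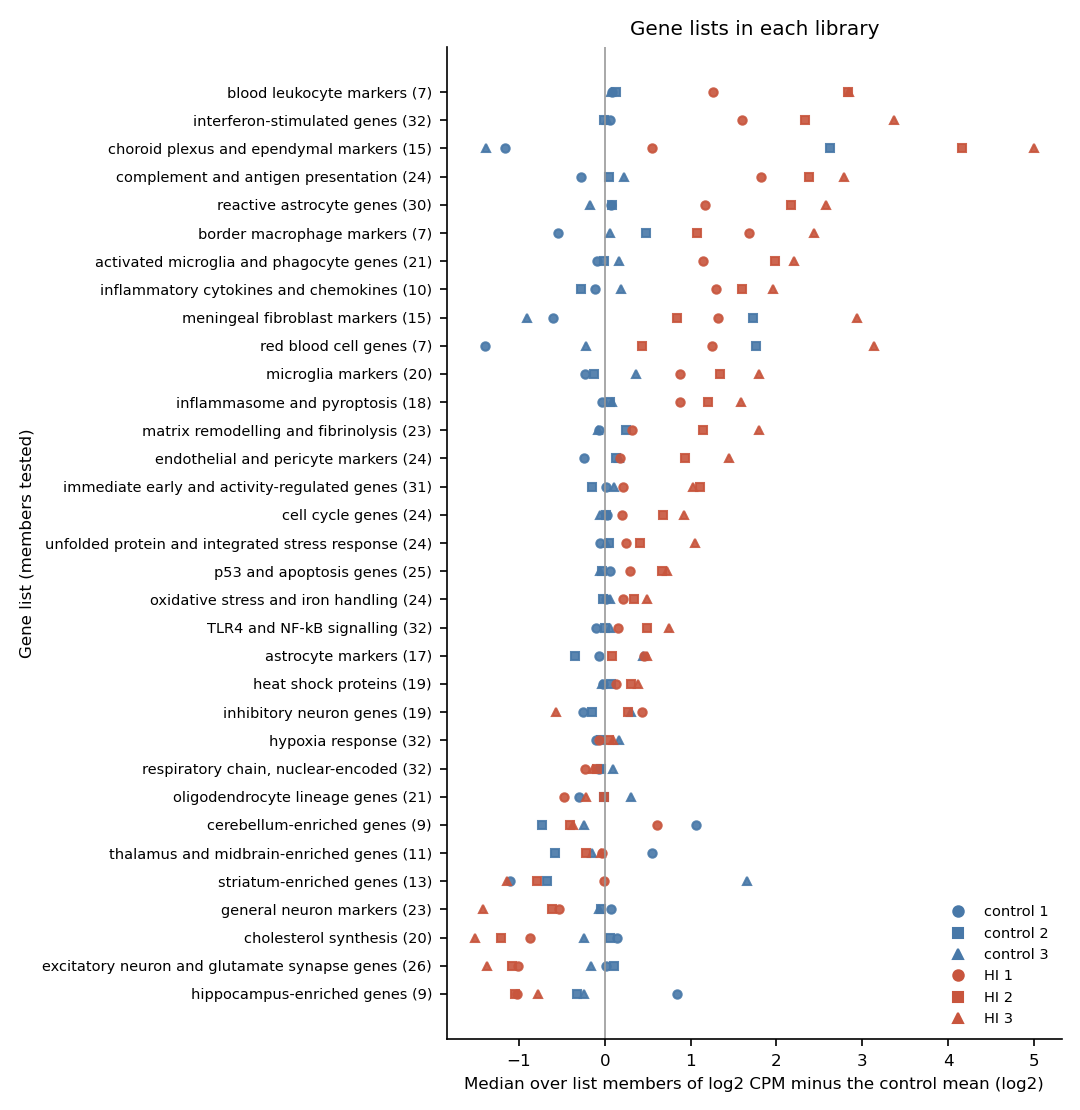
Median over the tested members of each gene list of log2 CPM minus the control mean, per library, with controls in blue and HI in red, and the number of members tested in brackets. The interferon list lies at 1.60, 2.33 and 3.37 in the HI libraries and near 0 in the controls, while the choroid plexus list is at 2.63 in control 2 and 0.55 in HI 1.

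Markers of neighbouring tissues and of other regions differed between libraries of the same group. Ttr, the transthyretin gene that choroid plexus epithelium expresses in bulk, had 50, 26868 and 7 reads in controls 1 to 3 and 2269, 115459 and 233214 in HI 1 to 3. Of 15 choroid plexus and ependymal markers 1 rose, Foxj1 of ciliated cells (5.26-fold), and 0 fell, the same adjusted over the list alone, with a median log2 fold change of 2.69 (camera adjusted p = 1.1e-03, and adjusted p = 0.53 with an estimated correlation). Otx2, Kcne2 and Folr1 had log2 fold changes of 2.65 ± 0.96, 2.60 ± 1.08 and 3.15 ± 1.35 that did not pass. Of 15 meningeal fibroblast genes 0 rose and 0 fell, over all genes and adjusted over the list alone, by edgeR, with 2 at an unadjusted p below 0.05 and 2 called by DESeq2, and a median of 1.57 (camera adjusted p = 0.011, and adjusted p = 0.63 with an estimated correlation). The call was lost without control 3 (camera adjusted p = 0.071) and without HI 3 (camera adjusted p = 0.11). Mgp, Igfbp2, Igf2 and Col3a1 had log2 fold changes from 1.79 to 2.62 and did not pass. Red blood cell genes had a median of 1.51, and 0 of 7 changed by edgeR over all genes or adjusted over the list alone, with 0 at an unadjusted p below 0.05 and 0 called by DESeq2 (camera adjusted p = 0.10). Slc4a1 and Alas2 had log2 fold changes of 1.81 ± 0.90 and 1.58 ± 0.99. The red cell list passed without control 2 (camera adjusted p = 1.1e-04) and without HI 2 (camera adjusted p = 0.022).

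Of 13 striatum-enriched genes 0 rose and 1 fell, the orphan receptor Gpr6 to 0.17 of the control level, the same adjusted over the list alone, with a median log2 fold change of -0.84 (camera adjusted p = 0.051). The striatum list was highest in control 3, at 1.65 above the control mean, and passed without control 1 (camera adjusted p = 1.2e-03), control 2 (4.7e-03) or HI 1 (0.011). Among 9 cerebellum-enriched genes 0 rose and 1 fell, Neurod1 to 0.148 of the control level, the same adjusted over the list alone (median -0.27, camera adjusted p = 0.33), and Grm4 had a log2 fold change of -0.92 ± 0.33. Of 11 thalamus and midbrain genes 0 changed by edgeR over all genes or adjusted over the list alone, with 2 at an unadjusted p below 0.05 and 2 called by DESeq2 (median -0.46, camera adjusted p = 0.85), and Slc18a2 and Rora had log2 fold changes of 1.88 ± 0.55 and -0.54 ± 0.16. Of 9 hippocampus-enriched genes 0 changed likewise, with 3 at an unadjusted p below 0.05 and 3 called by DESeq2 (median -1.44, camera adjusted p = 0.25), and Cabp7 and Lhx2 had log2 fold changes of -1.51 ± 0.55 and -1.44 ± 0.53. The sex-linked list had 3 tested members, of which 0 changed by edgeR, 0 were at an unadjusted p below 0.05 and 0 were called by DESeq2 (camera adjusted p = 0.56). Eif2s3y, on the Y chromosome, had 801 reads in control 3, 1063 in HI 2 and 1148 in HI 3 and 0 in the other libraries, and Kdm6a, the table's entry for the Y-linked list member Uty, was at 0 CPM in the same libraries as Eif2s3y, with a log2 fold change of 0.88 ± 1.81.

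Counts were repeated with these differences taken into account, in fits chosen after the data were seen. With the presence of Y-linked reads as a covariate edgeR called 774 genes, and with the median level of the choroid plexus list as a covariate 113, of which 90 were among the 2074. With the median level of the red blood cell list as a covariate 0 genes were called, the smallest adjusted p was 0.0890 and 3488 genes were at an unadjusted p below 0.05. Without control 2, HI 2 and HI 3, the libraries with most Ttr, 0 genes were called by edgeR and 1552 were at an unadjusted p below 0.05, and without controls 1 and 2, those with most Emx1, 0 were called and 2018 were at that level. All of the 2074 genes that could be tested kept their sign in each of these 5 fits. These genes were chosen on the same libraries, so a kept sign is not independent support.

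**Figure D3:**
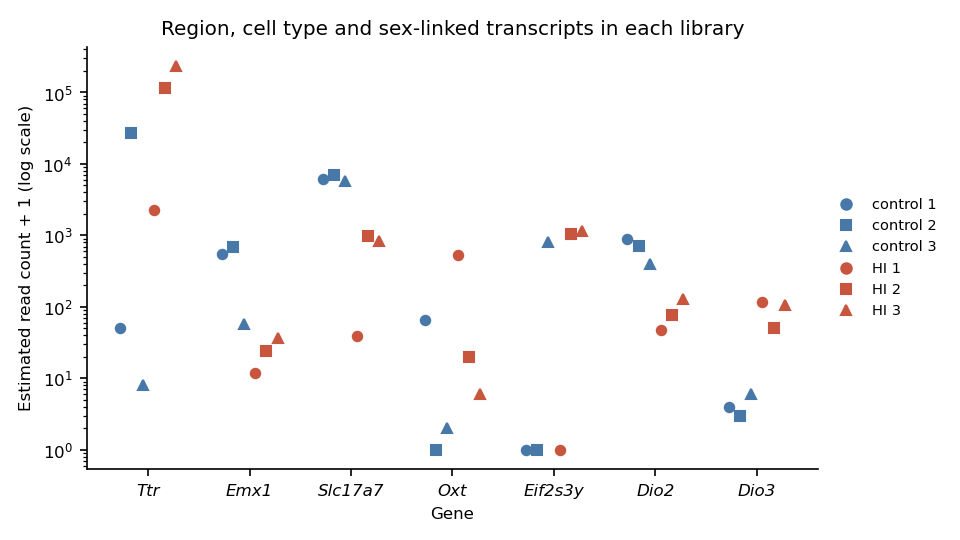
Estimated reads, plus 1 and on a log scale, of 7 genes in each library, with controls in blue and HI in red. Ttr is high in control 2, HI 2 and HI 3, Emx1 in controls 1 and 2, and Eif2s3y in control 3, HI 2 and HI 3, while Slc17a7 and Dio2 are lower and Dio3 higher in all HI libraries than in all controls.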

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

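The 5 fits with a covariate for Y-linked reads, for the choroid plexus list or for the red blood cell list, or with several libraries omitted were chosen only after the results were seen, and the others were planned. Depth limits the cytokine genes, of which 10 of 31 had enough reads to test. All of the 2074 called genes that were tested in a setting kept their direction there, which is weak evidence, as they were chosen on the same libraries. Under another scaling list medians changed sign for respiratory chain genes (0.04 with total counts) and HIF targets (-0.01 with DESeq2 size factors). Of the single named genes, 1567 of the planned repeats kept their side of the threshold, 426 lost a call and 59 gained one, and of the added repeats 252 kept it and 433 lost a call. Except where an alternative tests fewer libraries or another threshold, the cause was not tested.

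The count of 2074 changed genes was 0 at an adjusted p of 0.01 and 4366 at 0.1. DESeq2 called 4200 genes, 2076 higher and 2124 lower, with 1933 changed at least 2-fold, and limma-voom 1371, with 552 higher and 793 at least 2-fold. Total counts gave 2161 higher genes and a higher share of 74.7%, and upper-quartile factors 64.3%. DESeq2 size factors, no filter, the CPM filter and the robust dispersion gave 2064, 1831, 2070 and 2008. Leaving out 1 library gave 0 to 3689 changed genes, 0 to 2097 higher, 0 to 1592 lower and 0 to 2101 changed at least 2-fold by edgeR, with 3962 to 6391 genes at an unadjusted p below 0.05. The lowest, 0, came without control 1 and without HI 2, where the smallest edgeR adjusted p were 0.0775 and 0.0753, and these fits hold fewer libraries. The covariate for Y-linked reads left 774 genes (334 higher, 440 lower, 527 at least 2-fold) and that for choroid plexus 113 (45 higher, 68 lower, 109 at least 2-fold). That for red blood cells left 0, with 3488 at an unadjusted p below 0.05. Omitting control 2, HI 2 and HI 3, or controls 1 and 2, left 0 genes in each of these counts by edgeR, with 1552 and 2018 at an unadjusted p below 0.05. In the former fit HI 1 is a lone library assumed to vary like the controls, and in the latter control 3 is assumed to vary like the HI libraries.

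With the replicate number as a block 1723 genes were called (771 higher, 952 lower), of which 1383 were among the 2074. Deviations from the group mean correlated at 0.239, 0.073 and -0.146 between libraries of number 1, 2 and 3, and control 2 correlated best with HI 3 at 0.317. This does not show a pairing by number, but with 3 libraries per group it cannot exclude one. The block moved the astrocyte list to a camera adjusted p of 0.011 and the respiratory chain list to 0.082.

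With an estimated correlation 0 of 34 lists passed camera, with adjusted p from 0.41 to 0.94. It was 0.41 for microglia, phagocyte, leukocyte, complement, interferon, reactive astrocyte, cytokine, inflammasome, cholesterol and excitatory neuron genes, 0.45 for general neuron, 0.46 for border macrophage, oxidative stress and unfolded protein, 0.49 for heat shock and p53, 0.52 for matrix, 0.53 for choroid plexus, endothelial and TLR4, 0.54 for cell cycle, 0.56 for oligodendrocyte and 0.63 for meningeal and respiratory chain genes. By fry 2 lists passed. Its adjusted p was 0.056 for leukocyte, complement, inflammasome, cytokine and microglia, 0.057 for phagocyte, 0.058 for general neuron, heat shock, interferon, oxidative stress, p53 and reactive astrocyte, 0.059 for unfolded protein, 0.060 for border macrophage, 0.11 for TLR4, 0.12 for cell cycle and matrix, 0.13 for endothelial, 0.14 for respiratory chain, 0.15 for choroid plexus, 0.17 for oligodendrocyte and 0.26 for meningeal genes.

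Other settings moved few of the camera calls, and 21 to 27 lists passed. The respiratory chain list was at 0.11 with upper-quartile factors, 0.30 with total counts and 0.054 with the choroid plexus covariate, and the meningeal list at 0.087 with total counts and 0.17 with that covariate. The striatum list passed with upper-quartile factors (0.017), total counts (5.4e-03), no filter (0.029), the Y-linked covariate (0.024) and without controls 1 and 2 (1.9e-16), and the red cell list with no filter (0.028), without control 2, HI 2 and HI 3 (3.0e-07) and without controls 1 and 2 (1.6e-03). With the choroid plexus covariate the astrocyte list passed (9.3e-03) and the choroid plexus list itself was at 0.14. With the red blood cell covariate the immediate early list passed (0.044) and the meningeal list was at 0.13. Without control 2, HI 2 and HI 3 the cell cycle list was at 0.22, endothelial and TLR4 at 0.086 and p53 at 0.055, and without controls 1 and 2 the inhibitory neuron list passed at 0.033. Leaving out 1 library gave camera adjusted p of 1.4e-03 to 0.40 for astrocyte, 4.0e-03 to 0.18 for immediate early, 7.7e-07 to 0.11 for meningeal, 3.6e-05 to 0.13 for oligodendrocyte, 1.1e-04 to 0.42 for red cell, 5.4e-03 to 0.13 for respiratory chain and 1.2e-03 to 0.43 for striatum genes, and from 22 to 26 lists passed.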

Other observations

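The tests of explanations, the fits with a covariate and the counts over other splits in this part were chosen only after the results were seen, and the lists of cortex, hypothalamus, basal forebrain and Y-linked genes and the genes named here were chosen after their values were seen. The test on cortex genes was also widened by Slc17a7 and Epha4 after its first result was seen, which left its outcome on the same side, and the synapse tests were run again over members whether called or not, which left gene span on the same side. Dio3, which inactivates thyroid hormone, rose from 0.25 ± 0.12 to 5.77 ± 2.35 CPM (SD, n = 3 per group, edgeR adjusted p = 0.0198), from 3, 2 and 5 reads in the controls to 115, 49 and 107 in HI, while the activating enzyme Dio2 had 896, 706 and 396 reads against 46, 77 and 129. Klf9 and Hr, which thyroid hormone induces in brain, fell to 0.309 and 0.258 of the control level (edgeR adjusted p = 0.0196 and 0.0475), although Hr was as low in control 3 (238 reads) as in HI 1 (238 reads). Acss1, a mitochondrial enzyme that makes acetyl-CoA from acetate, rose 3.33-fold with little spread, from 25.8 ± 1.88 to 86.1 ± 11.4 CPM (edgeR adjusted p = 0.0196).

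Of 20 cerebral cortex genes 0 rose and 7 fell, or 0 and 17 adjusted over the list alone, with a median log2 fold change of -1.98 (camera adjusted p = 4.8e-10, and adjusted p = 0.24 with an estimated correlation), and 8 of the 20 are also in a fixed list. Their median, relative to the control mean, was 0.47 and 0.48 in controls 1 and 2, -0.83 in control 3 and -2.60, -1.35 and -1.65 in HI 1 to 3. Of 17 hypothalamus genes 2 rose and 0 fell, the same adjusted over the list alone, with a median of 2.31 (camera adjusted p = 3.1e-04, and adjusted p = 0.40 with an estimated correlation), and the genes that rose were Irs4 (18.5-fold) and Fezf1. The median of the hypothalamus list, relative to the control mean, was 0.43, -1.37 and 0.23 in controls 1 to 3. In HI 1 to 3 it was 3.66, 1.72 and 1.23, so every HI library lay above every control. Oxt and Avp, hormones of the hypothalamus, had 530 and 1567 reads in HI 1 against at most 64 and 83 in any other library. The basal forebrain and Y-linked lists did not pass (camera adjusted p = 0.68 and 0.66). These p-values test lists built after the values were seen, so they are not independent evidence. They were adjusted over the 4 added lists alone and are not comparable with those of the fixed lists.

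The fall of glutamate synapse genes was set against 3 explanations, and that of cortex genes only against less cerebral cortex in the tissue taken. Poorer detection of genes with a long span is argued against by the 17 members of the excitatory list that are not transcription factors, called or not. Their median differed by -1.002 from genes of the same span (95% bootstrap interval -1.39 to -0.47). All genes of the lowest and highest span decile had medians of 0.088 and -0.215. Transcript length and RNA quality were not tested. Less cerebral cortex in the tissue taken may contribute, since cortex genes other than those that prompted the test were also lower in control 3 than in controls 1 and 2 (-0.77, interval -2.06 to -0.28, 18 genes), but for the 17 members the same difference was 0.088 (interval -0.35 to 0.42), and since control 3 is a single library it cannot be told whether less cortex took part in their fall. A loss of neurons of every kind also stays open, since the inhibitory neuron list had a median of 0.085 (interval -0.38 to 0.35) where general neuron markers were at -0.85, but against control 3 alone -0.54 and -0.73, was at 0.44, 0.27 and -0.56 in HI 1, 2 and 3 relative to the control mean and passed camera without controls 1 and 2 (adjusted p = 0.033). An effect of the injury on excitatory neurons was not tested apart from these, as the labels do not give the region taken.

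Choroid plexus epithelium genes, high in the HI group as a whole, were high together in single libraries of both groups. Control 2 exceeded controls 1 and 3 by a median log2 difference of 4.47 (95% bootstrap interval 2.68 to 5.64, 12 genes, without the ciliated-cell genes), which is consistent with choroid plexus carried into some of the tissue pieces, a candidate explanation found and tested on the same libraries. A response shared by the HI libraries stays open beside it, since HI 1 differed from control 2 by -2.69 (interval -3.49 to -1.91) but lay above controls 1 and 3 by 1.76 (interval 0.86 to 2.51). Ttr, its most abundant transcript, took 0.183% of the reads in control 2, 0.0158% in HI 1, 0.783% in HI 2 and 1.56% in HI 3, and had 50 and 7 reads in controls 1 and 3.

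The rise of microglia, phagocyte and interferon genes was set against 3 explanations, over all 73 tested members of these lists. Their median log2 fold change was 2.17 (95% bootstrap interval 1.97 to 2.50). It was 1.58 (interval 1.41 to 1.87) with the choroid plexus index as a covariate and 1.94 (interval 1.65 to 2.21) with the red blood cell index. With the presence of Y-linked reads it was 1.81 (interval 1.66 to 2.12). The intervals cover the spread between genes and not that between libraries. The plexus index was 1.075, 4.632 and 0.642 in controls 1 to 3 and 2.165, 5.87 and 6.773 in HI 1 to 3, so it partly followed the group. These fits therefore cannot tell whether carry-over of plexus, blood left in the tissue or a difference in sex caused the rise, in whole or in part. The interferon list passed camera in each of these fits (adjusted p = 3.8e-16, 3.1e-20 and 3.7e-20, against adjusted p = 0.41 with an estimated correlation and no covariate), but members called higher went from 54 to 2, 0 and 26, in fits with smaller folds, a median SE of 0.46, 0.45 and 0.38 against 0.41, and 1 residual degree of freedom fewer. A response of resident or entering immune cells to the injury remains a hypothesis that may account for the rise, raised on these same 6 libraries and not itself tested. Differences in the region taken and in the age of the controls stay open and were not tested.

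The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2074 changed genes and the highest other 5, and 1237 genes changed at least 2-fold against 5, so that 1 of 10 splits, the real one, was as large in each case. For lists passing camera with the preset correlation the real split gave 24 and the highest other 28, and 4 of 10 splits gave at least 24. The split with 28 set control 1, control 3 and HI 1 against the libraries with most Ttr, control 2, HI 2 and HI 3, which points to a structure of the samples that the preset correlation does not allow for.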
